A study of Mus musculus with 72 samples.

How the data were processed

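The deposited file holds 1 column of values for each of the 72 brain libraries and 18006 genes by symbol. Another 3 columns of values match no sample in the labels and were not used. The labels describe perfused brain tissue, QuantSeq 3' mRNA libraries made with a unique molecular identifier module, and processing by the authors with FastQC, Trim Galore 0.5.0, STAR 2.6.0, featureCounts and DESeq2 1.22.2 on GRCm38. They do not say whether identifiers were used to collapse reads, which strand was counted, which genes were filtered or which annotation was used.

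The deposited values are on the log2 scale, after the authors' variance-stabilizing transform of counts divided by a size factor per library. This was tested on the values themselves. One transform with 1 size factor per library returned whole reads for 100.0% of the values within 1e-06, and 0 reads stood at 4.21, the lowest value, with 17.83 the highest. The recovered reads sum to 1315669 to 3963491 per library, median 3046915, and 5 genes have no read in any library. Correlations between libraries across genes were 0.957 to 0.9927, where genes are not independent replicates. Levels in the text are normalized reads, the recovered reads divided by the library's size factor, with SD over libraries. A gene at 0 reads in a library could have up to 3 expected reads there, and such limits cover counting error only. The transform compresses fold changes of genes with few reads. On simulated data a 2-fold change was fitted with a median log2 fold change of 0.76 to 0.79 and a 1.5-fold change with 0.43 to 0.46.

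Tests used limma 3.58.1 in R 4.3.3 on the deposited values (lmFit, contrasts.fit and eBayes with trend, two-sided), with the 5 groups, sex and title series (O795 to O847 against O921 to O940, taken from the sample titles) as terms and all 72 libraries in 1 fit. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 18006 genes of a comparison. The p-values measure the spread between libraries. Sex differences in the effects were tested with a mean for each group and sex. The tests, gene lists, rule for named genes and alternatives were chosen before the data were examined, except those named as added. In the self-test 200 of 18006 genes were changed in simulated values. At 2-fold 97.5% to 100% were recovered, and at 1.5-fold 66% to 99.5%, depending on the comparison. Only genes with a mean of at least 20 normalized reads were changed. Each gene had a smoothed spread and no differences between title runs were simulated, so recovery in the real data may be lower. The false calls numbered 6 to 22 per comparison, which in some comparisons is more than the nominal share, so called genes near the threshold are less certain.

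Gene lists for cell types, brain regions and pathways were tested with camera at its preset correlation of 0.01, with the same variance trend (a choice made with the data in hand), adjusted over 266 tests of 38 lists in 7 comparisons. Lists with fewer than 5 measured members were not tested. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, stand beside it. Of the 266 tests camera called 66, camera with an estimated correlation 5 and fry 11.

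Named genes follow a rule: the genotype check genes, up to 8 called genes per direction with the largest change, and from each list up to 4 called members, or 2 uncalled ones as values. It gives more genes than the text holds, and the subset in the text was picked after the values were seen. Some genes that the rule gives are not reported here. Genes named outside the rule are said to be so. Positions come from GENCODE for GRCm38. Dixon's ratio was used to find libraries far from the others in the groups of 7.

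Alternatives were no title series term, 1 title series, only the compared groups, 1 sex, no sex term, dropping the genes with the lowest means (13504 kept), eBayes without trend or robust, sample weights, median centring, quantile normalization and leaving out each unoperated or anesthesia library. Added after seeing the data were fits without the 13 WT CLP libraries titled O795 to O807, within titles O817 to O847 (also without 5xFAD unoperated library 2, the shallowest), with 3 title runs as the term, with a cerebellum score, with a residual axis score, with the sex of 5xFAD CLP libraries 7 and 8 taken from their transcripts or those libraries left out, and limma voom on recovered reads (12888 genes with at least 10 reads in 7 libraries). The residual axis is the first axis of the within-group residuals of genes with a mean of at least 20 normalized reads and holds 19.1% of their variance. A library's score on it was taken from its full values, not its residuals, so the score also carries differences between groups. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and the R package data.table (version 1.17.8). All 72 libraries were kept.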

Results

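RNA was measured in 72 perfused mouse brain samples with QuantSeq, a method that reads the 3' ends of polyadenylated transcripts. The mice were C57BL/6 (WT) or 5xFAD, an amyloid model that carries human transgenes with familial Alzheimer's disease mutations in mouse Thy1 expression cassettes. Treatments were cecal ligation and puncture (CLP), an abdominal surgery that causes polymicrobial sepsis, anesthesia alone, or no operation, and the study sampled brains 25 days after CLP. The groups held 30 WT CLP, 7 WT unoperated, 21 5xFAD CLP, 7 5xFAD anesthesia and 7 5xFAD unoperated libraries, with 32 female and 40 male animals in all. Recovered reads ran from 1315669 to 3963491 per library with a median of 3046915. The ranges were 2377836 to 3963491 in WT CLP, 2623704 to 3633338 in WT unoperated, 2565250 to 3527961 in 5xFAD CLP, 2823163 to 3858676 in 5xFAD anesthesia and 1315669 to 3522734 in 5xFAD unoperated.

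Genotype was visible in the transcripts of the transgene cassettes. Thy1 (chromosome 9, 44043384 to 44048579, plus strand, GRCm38) averaged 8630 ± 1690 normalized reads (SD, n = 35) in 5xFAD libraries, where the lowest value was 6545, and 2780 ± 340 (n = 37) in WT libraries, where the highest was 3789. App (chromosome 16, 84949685 to 85173766) averaged 3330 ± 730 in 5xFAD and 3110 ± 722 in WT. Sex-linked transcripts matched the label in 70 libraries. The other 2 were 5xFAD CLP library 7, labelled male with 960 normalized reads of Xist, and 5xFAD CLP library 8, labelled female with 2.51. The labels name brain as the tissue while the extraction protocol names lung. Of 10 lung marker genes 5 were measured, with means of 0.13 to 1.5 normalized reads and a highest single value of 7.87, for Napsa.

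The labels give no batch, but the numbers in the sample titles fall into 3 runs. Titles O795 to O816 hold 13 WT CLP and 9 5xFAD CLP libraries. Titles O817 to O847 hold both genotypes with and without CLP, as 7 WT unoperated, 8 WT CLP, 7 5xFAD unoperated and 8 5xFAD CLP libraries. Titles O921 to O940 hold 9 WT CLP, 4 5xFAD CLP and all 7 anesthesia libraries. Cerebellar transcripts differed between the last run and the other titles. Gabra6, a GABA receptor subunit of cerebellar granule cells, had a median of 79.3 normalized reads there and 0 elsewhere, and Cbln3 had 351 and 3.14. In limma the term for this split passed an adjusted p of 0.05 in 4555 genes, 2304 of them higher in the last run.

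A second division of the libraries lay inside WT CLP. The 13 WT CLP libraries titled O795 to O807 held 33.3 ± 6.13 normalized reads of Wdfy1 (chromosome 1, 79702262 to 79776143), against 130 ± 19.8 in the other 17 WT CLP libraries and at least 96.4 in each of the other 59 libraries. Gabra2, a GABA receptor subunit, and Nnt, a mitochondrial transhydrogenase, were also lower there, at 84.2 ± 8.84 against 195 ± 30.6 and at 34.5 ± 5.69 against 63.2 ± 9.93. These genes were singled out after their values were seen. The 9 5xFAD CLP libraries of the same title run did not share the low Wdfy1.

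**Figure D1:**
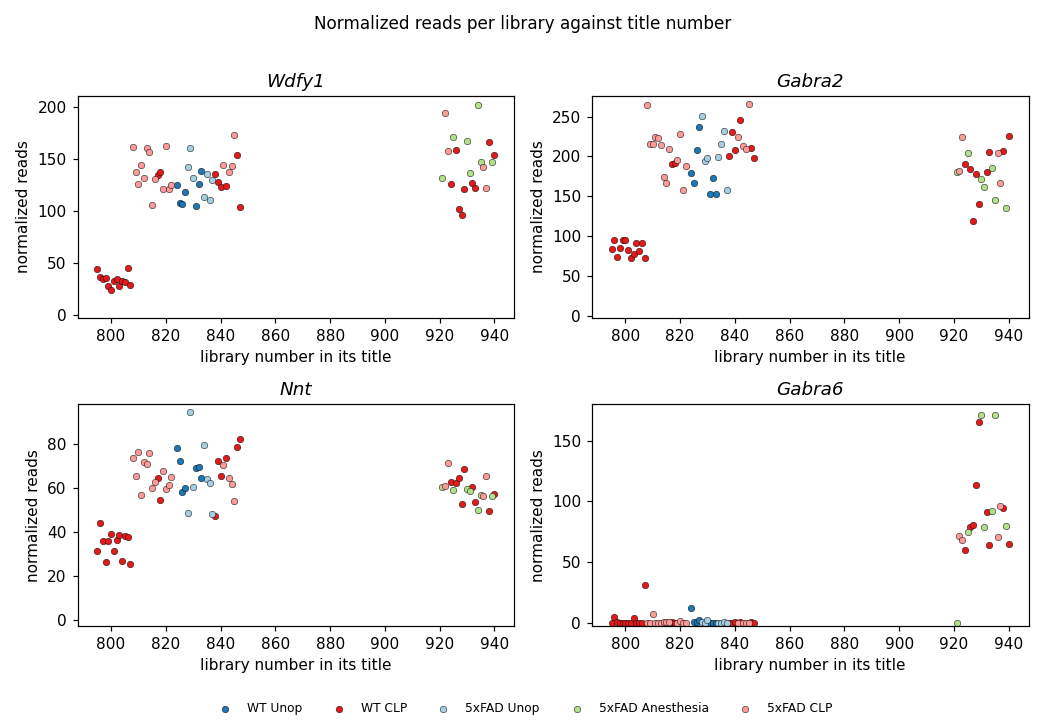
Normalized reads (y axis) of Wdfy1, Gabra2, Nnt and Gabra6 in each of the 72 libraries against the number in its title (x axis), coloured by group. The 13 WT CLP libraries with the lowest numbers stand below all others in Wdfy1, Gabra2 and Nnt, and Gabra6 has a median of 79.3 reads in the last run of titles and 0 in the others.

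The first comparison asks what the 5xFAD genotype changes in brains without an operation (7 libraries against 7). Unoperated 5xFAD brains had more transcript of 4 genes, Thy1, Ccl3 and Ccl6 among them, and no gene was called lower. Thy1 rose by 1.56 ± 0.11 (log2 fold change ± SE, adjusted p = 1.81e-18), from 2960 ± 338 to 9040 ± 2730 normalized reads. Ccl3 (chromosome 11, 83647844 to 83649355) and Ccl6 (chromosome 11, 83587882 to 83593087), which encode chemokines made by activated microglia, rose by 0.79 ± 0.13 (adjusted p = 9.86e-05) and 1.09 ± 0.22 (adjusted p = 0.0153). Ccl6 went from 6.51 ± 1.99 to 43.9 ± 27.1 normalized reads, and the lowest 5xFAD library, at 10.5, lay next to the highest WT library, at 10.8. App itself had a log2 fold change of 0.43 ± 0.14 (adjusted p = 0.644).

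Gene lists were called with a preset correlation only, and none of the 8 calls held with an estimated one. Of 30 disease-associated microglia genes 2 rose over all genes, and 13 rose when adjusted over the list alone. The list rose by camera (mean log2 fold change 0.34, adjusted p = 1.11e-19), with an adjusted p = 0.0567 with an estimated correlation. Homeostatic microglia genes rose as a list (adjusted p = 1.97e-06, and adjusted p = 0.214 with an estimated correlation). None of its 15 members passed over all genes and 4 passed adjusted over the list alone. Cholesterol synthesis genes rose as a list too (adjusted p = 5.49e-07, and adjusted p = 0.214 with an estimated correlation), where 0 of 17 passed over all genes and 7 adjusted over the list alone. Msmo1 and Nsdhl, enzymes of that pathway, had values of 0.34 ± 0.11 and 0.30 ± 0.10. MHC class I (11 measured) rose at an adjusted p = 0.00025, and adjusted p = 0.301 with an estimated correlation, where 0 members passed either way and B2m had 0.39 ± 0.15. Interferon response genes (27 measured) rose at an adjusted p = 0.000432, and adjusted p = 0.494 with an estimated correlation, with 0 members over all genes and 1 adjusted over the list alone. Complement (16 measured) rose at 0.00569, and adjusted p = 0.44 with an estimated correlation, with 0 and 2 members, and C1qc had a log2 fold change of 0.61 ± 0.16. Reactive astrocyte genes (22 measured) rose at 0.00607, and adjusted p = 0.413 with an estimated correlation, with 0 and 2 members. Gfap, the astrocyte intermediate filament, had 0.82 ± 0.25, and 5xFAD unoperated library 6 alone held 1320 normalized reads of it. Cytokine and acute phase genes (25 measured) rose at 0.0112, and adjusted p = 0.327 with an estimated correlation, with 0 members either way.

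In limma 4 of 18006 genes passed an adjusted p of 0.05 and 1162 an unadjusted p of 0.05, and limma voom on the recovered reads gave 3. The call of Ccl6 ended without 5xFAD unoperated library 2, 3 or 6, with log2 fold changes of 0.98, 1.05 and 1.0, and its adjusted p ran from 0.000179 to 1 over the alternatives. With the 7 libraries per group analysed alone only Thy1 passed.

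**Figure D2:**
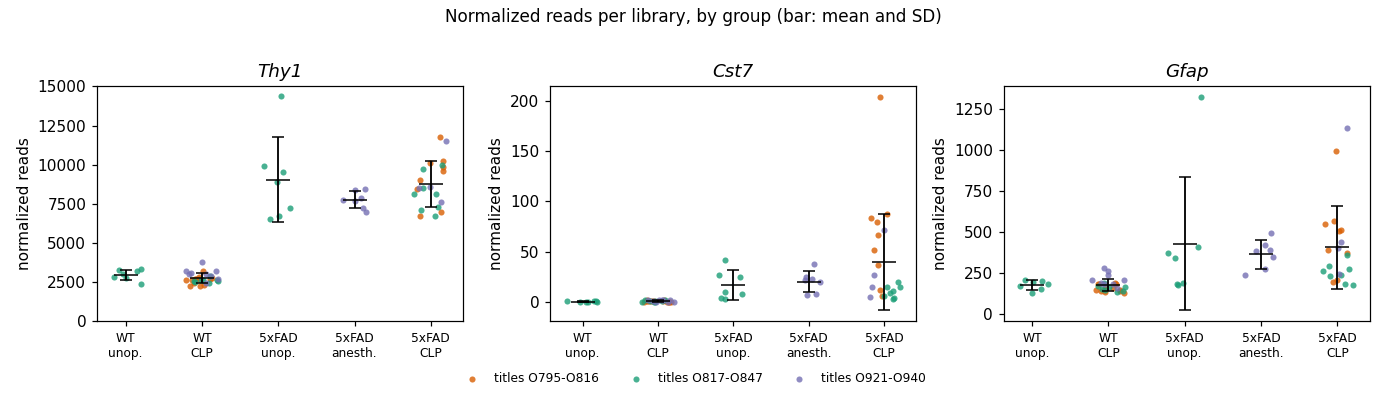
Normalized reads per library (y axis) of Thy1, Cst7 and Gfap in the 5 groups (x axis), coloured by title run, with bars for the mean and SD. Thy1 lies at 6545 or above in each 5xFAD library and at 3789 or below in each WT library, while Cst7 and Gfap spread widely among 5xFAD libraries.

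The second comparison asks the same of sepsis survivors, 21 5xFAD CLP against 30 WT CLP libraries. Among these mice 5xFAD brains had higher transcripts of microglia and of cholesterol synthesis. Lower inhibitory neuron genes were called too, but not without the 13 WT CLP libraries described above. Single complement and reactive astrocyte genes were higher too, while the calls of these 2 lists were lost with an estimated correlation. Cst7 (chromosome 2, 150570415 to 150578944), a cystatin of plaque-associated microglia, rose from 0.896 ± 0.796 to 39.4 ± 47.7 normalized reads (log2 fold change 1.39 ± 0.15, adjusted p = 6.53e-11). Gfap (chromosome 11, 102887336 to 102900912) rose from 175 ± 36.7 to 406 ± 251 (0.96 ± 0.13, adjusted p = 6.51e-07). Thy1 rose by 1.67 ± 0.06 (adjusted p = 3.81e-37), while App had 0.03 ± 0.08 (adjusted p = 0.932).

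Of 30 disease-associated microglia genes 18 rose and none fell, and 24 rose when adjusted over the list alone (camera adjusted p = 7.2e-52, and adjusted p = 0.000216 with an estimated correlation). They included Ccl6 (1.01 ± 0.12), Clec7a, a pattern recognition receptor (0.89 ± 0.12), and the chemokines Ccl4 (0.77 ± 0.09) and Ccl3 (0.71 ± 0.07). The receptor Trem2 rose by 0.70 ± 0.09 and its signalling adaptor Tyrobp by 0.90 ± 0.11. Homeostatic microglia genes rose as well, 7 of 15 over all genes and 14 adjusted over the list alone (camera adjusted p = 2.9e-19, and adjusted p = 0.00205 with an estimated correlation), with the growth factor receptor Csf1r at 0.39 ± 0.07. Among complement genes 6 of 16 rose, 7 adjusted over the list alone, with C1qa at 0.56 ± 0.10, C4b at 0.54 ± 0.09 and C1qc at 0.51 ± 0.09 (list adjusted p = 3.65e-08, and adjusted p = 0.0611 with an estimated correlation). Among reactive astrocyte genes 4 of 22 rose, 8 adjusted over the list alone, among them the protease inhibitor Serpina3n at 0.64 ± 0.10 and the lysosomal protease Ctsd at 0.53 ± 0.09 (list adjusted p = 8.16e-06, and adjusted p = 0.15 with an estimated correlation). Cholesterol synthesis genes rose, 6 of 17 over all genes and 12 adjusted over the list alone (list adjusted p = 7.71e-16, and adjusted p = 0.00824 with an estimated correlation), with Sqle, which encodes squalene epoxidase, at 0.28 ± 0.05.

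The called falls were small. The neuropeptide gene Cort fell by 0.39 ± 0.08, the neprilysin gene Mme, whose product degrades amyloid peptide, fell by 0.31 ± 0.05, the potassium channel gene Kcnj4 fell by 0.31 ± 0.07, and the neuropeptide precursor gene Vgf fell by 0.29 ± 0.07. Of 14 inhibitory neuron genes 3 fell, Cort, Sst (by 0.22 ± 0.05) and Crh (by 0.18 ± 0.05), and 6 fell adjusted over the list alone (list adjusted p = 3.25e-05, and adjusted p = 0.00822 with an estimated correlation). Without the 13 WT CLP libraries the log2 fold change of Cort was -0.08 and that of Sst -0.20, neither past the threshold, the list had an adjusted p = 0.0688 (0.16 within titles O817 to O847), and Mme still fell by 0.30. Wdfy1, called at 0.76 ± 0.12, had 0.12 without them. Another 10 lists were called with the preset correlation and none of them with an estimated one. Among them myelinating oligodendrocyte genes fell (adjusted p = 0.000919, and adjusted p = 0.3 with an estimated correlation) with 0 of 16 members over all genes or adjusted over the list alone, and had an adjusted p = 0.99 without the 13 libraries and 0.0948 within titles O817 to O847.

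In limma 167 of 18006 genes passed, 129 higher and 38 lower in 5xFAD, and the called genes had a median absolute log2 fold change of 0.24 as fitted. Without the 13 WT CLP libraries 42 genes passed, 35 of them among the 167, with Cst7 at 1.35, Gfap at 0.96 and Trem2 at 0.72 still called. Serpina3n (0.54), C1qa (0.48), C4b (0.43), C1qc (0.35), Csf1r (0.32), Kcnj4 (-0.31), Vgf (-0.31) and Crh (-0.09) were not called then. Within titles O817 to O847 (8 against 8) 2 genes passed, Thy1 (1.62) among them, and Cst7 had 0.75, Gfap 0.54, Trem2 0.43, Tyrobp 0.42 and C1qc 0.10, none of them called, while within titles O921 to O940 (4 against 9) only Thy1 passed. The disease-associated microglia list had an adjusted p = 9.63e-13 within titles O817 to O847 and 1.21e-42 without the 13 libraries.

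The third comparison asks what CLP leaves in the WT brain after 25 days, 30 WT CLP against 7 WT unoperated libraries. It holds surgery and any anesthesia as well as sepsis, and WT has no anesthesia group. Single genes of neutrophils, of acute inflammation and of endothelium were higher after CLP, but of these lists only that of cytokines and acute phase held with an estimated correlation. S100a8 and S100a9 (chromosome 3, 90668978 to 90670035 and 90692632 to 90695721), which encode the calprotectin subunits abundant in neutrophils, rose by 1.59 ± 0.29 (adjusted p = 0.00109) and 1.41 ± 0.28 (adjusted p = 0.00165). S100a8 had 13.8 ± 10.4 normalized reads without operation (n = 7), and 10.5 to 498 after CLP with an SD of 95.4 (n = 30). Lcn2 (chromosome 2, 32384633 to 32388252), an iron-binding acute phase gene, rose by 1.05 ± 0.21 (adjusted p = 0.00166), from 2.29 ± 6.05 to 18.5 ± 17.4. Selp, the endothelial adhesion gene P-selectin, was at 0 reads in each unoperated library and at 3.35 ± 4.79 normalized reads after CLP (adjusted p = 0.00626).

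Of 12 neutrophil genes 9 rose over all genes and 9 adjusted over the list alone (list adjusted p = 3.65e-08, and adjusted p = 0.214 with an estimated correlation). Cytokine and acute phase genes rose, 8 of 25 over all genes and 9 adjusted over the list alone (adjusted p = 1.14e-05, and adjusted p = 0.0491 with an estimated correlation), among them the chemokine gene Ccl12 at 0.60 ± 0.11 and the interleukin-1 receptor gene Il1r1 at 0.36 ± 0.08. Endothelial activation genes rose (adjusted p = 0.02, and adjusted p = 0.432 with an estimated correlation), 3 of 12 over all genes and 3 adjusted over the list alone. Glucocorticoid response genes rose (adjusted p = 0.00996, and adjusted p = 0.541 with an estimated correlation), 3 of 16 over all genes and 6 adjusted over the list alone, with the kinase gene Sgk1 (chromosome 10, 21882184 to 21999903) at 0.60 ± 0.12. MHC class I genes rose (adjusted p = 0.00176, and adjusted p = 0.343 with an estimated correlation), 3 of 11 over all genes and 6 adjusted over the list alone, with H2-D1 at 0.51 ± 0.13. Interferon response genes rose at an adjusted p = 0.0169, and adjusted p = 0.692 with an estimated correlation, with 1 of 27 members either way. Oxidative phosphorylation genes rose at 0.00371, and adjusted p = 0.604 with an estimated correlation, with 2 of 34 members either way. The 2 called over all genes, Ndufa1 (0.84 ± 0.23) and Ndufa4 (0.53 ± 0.13), had 0.04 and 0.10 with a score for the main axis of residual variation as a term and were not called. The call of Ndufa1 also ended without WT unoperated library 2 (0.74), 3 (0.65) or 5 (0.74). The monocyte gene Ly6c2 rose by 0.44 ± 0.11 and the endothelial gene Ly6c1 by 0.43 ± 0.11.

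The largest changes also held genes outside these groups. Snhg8, a host gene of small nucleolar RNA, rose by 1.74 ± 0.39, Cox17, a copper chaperone, by 1.30 ± 0.31, Nr4a1, an immediate early transcription factor, by 1.13 ± 0.26, and Hnrnpa1, an RNA-binding protein, by 1.09 ± 0.25. Gad1, which encodes a GABA-synthesizing enzyme, rose by 0.83 ± 0.17 and the synaptic gene Snap25 by 0.41 ± 0.09. Atp9a, a phospholipid flippase, fell by 0.52 ± 0.10, the potassium channel partner Kcnip2 fell by 0.47 ± 0.11, the astrocyte gene Mlc1 fell by 0.41 ± 0.08 and the postsynaptic gene Nrgn fell by 0.29 ± 0.07 (-0.10 and not called with quantile normalization). Wdfy1 fell by 0.65 ± 0.17, and its log2 fold change was 0.08 without the 13 WT CLP libraries. With the residual axis score as a term Snhg8 had 0.44, Nr4a1 0.40, Cox17 0.26, Hnrnpa1 0.22, Gad1 0.19 and Snap25 0.13, none of them called. H2-D1 (0.22), Atp9a (-0.33), Mlc1 (-0.27), Kcnip2 (-0.21), Nrgn (-0.16), Ccl12 (0.50), Sgk1 (0.47), Ly6c2 (0.39), Ly6c1 (0.38) and Selp lost their calls with it as well, while S100a8, S100a9, Lcn2 and Il1r1 kept theirs. On that axis WT unoperated libraries 2, 3 and 5 stood at -1.72, -2.40 and -1.39, and the other 4 of the group at -0.55 to 0.39. The score also carries differences between the groups, so a call lost with it can be an effect of CLP taken out.

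In limma 1555 of 18006 genes passed, 919 higher and 636 lower, with a median absolute log2 fold change of 0.27 as fitted. Without the 13 WT CLP libraries 140 genes passed, without WT unoperated library 2 or 3 the counts were 690 and 679, without library 5 of that group 502 genes were higher and 311 lower, and with the residual axis score as a term 17 passed. Within titles O817 to O847 (8 against 7) 64 genes passed, 49 of them among the 1555. Selp, Lcn2 (1.27 ± 0.18), S100a8 (1.43 ± 0.26), S100a9 (1.26 ± 0.20) and Sgk1 (0.66 ± 0.14) were among them, while Snhg8 (1.44), Nr4a1 (1.10), Cox17 (0.99), Hnrnpa1 (0.90), Gad1 (0.70), Il1r1 (0.41), H2-D1 (0.41), Snap25 (0.30), Nrgn (-0.22), Kcnip2 (-0.28), Mlc1 (-0.34) and Atp9a (-0.48) were not.

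**Figure D3:**
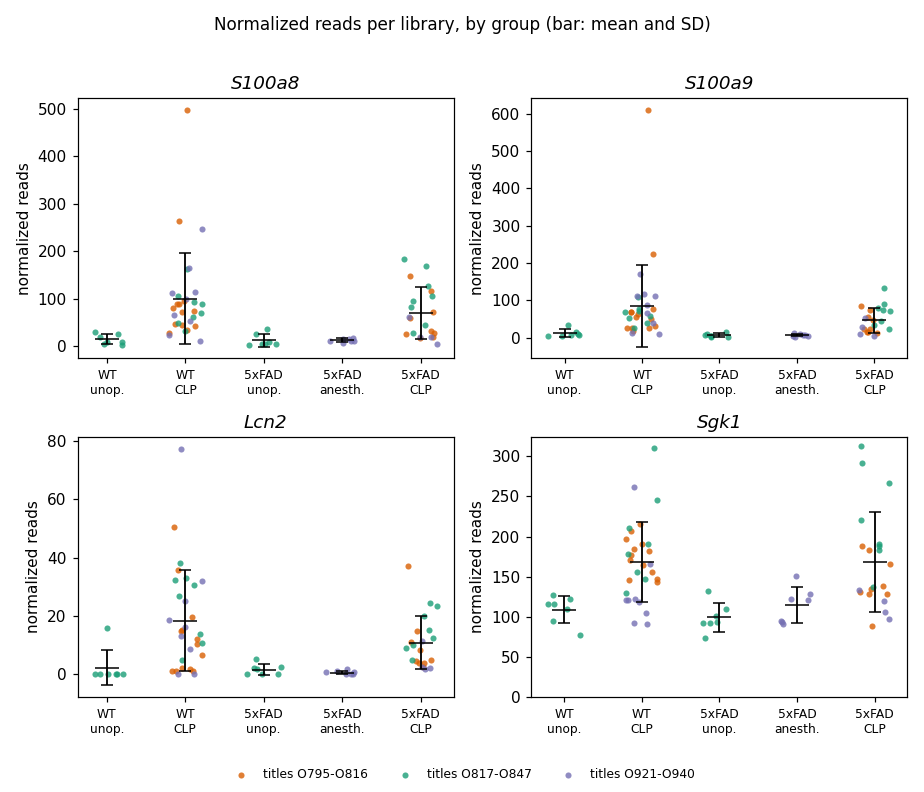
Normalized reads per library (y axis) of S100a8, S100a9, Lcn2 and Sgk1 in the 5 groups (x axis), coloured by title run, with bars for the mean and SD. After CLP the libraries spread upward from the unoperated range in both genotypes, with S100a8 at 10.5 to 498 in WT CLP and 5.1 to 184 in 5xFAD CLP.

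The fourth comparison asks what CLP leaves in the 5xFAD brain, 21 5xFAD CLP against 7 5xFAD unoperated libraries. It holds surgery and any anesthesia as well as sepsis. S100a8 rose by 1.33 ± 0.30 (adjusted p = 0.0207), from 11.9 ± 13.2 to 69.2 ± 54.5 normalized reads, and S100a9 by 1.21 ± 0.28 (adjusted p = 0.0272). Scgb3a1 (chromosome 11, 49663610 to 49665118), a secretoglobin, rose by 0.89 ± 0.21 (adjusted p = 0.0292) from 0.299 ± 0.79 to 12.3 ± 16.0. Most of this rise lay in titles O817 to O847, where the 8 5xFAD CLP libraries averaged 29.5 ± 13.3. Sgk1 rose by 0.63 ± 0.13 (adjusted p = 0.0126) and the ceramidase gene Acer2 by 0.55 ± 0.12 (adjusted p = 0.0207). The selenium transport gene Sepp1 rose by 0.42 ± 0.09. The myelin genes Cnp and Mag fell by 0.47 ± 0.10 and by 0.33 ± 0.08, respectively, Gpr17, a receptor of maturing oligodendrocyte precursors, fell by 0.39 ± 0.08, the glycine transporter gene Slc6a9 fell by 0.38 ± 0.08, and the astrocyte gene Mlc1 fell by 0.32 ± 0.08.

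Of 12 neutrophil genes 2 rose over all genes and 3 adjusted over the list alone (list adjusted p = 1.2e-05, and adjusted p = 0.318 with an estimated correlation). Glucocorticoid response genes rose (adjusted p = 0.00222, and adjusted p = 0.439 with an estimated correlation), 1 of 16 over all genes and 4 adjusted over the list alone. Oxidative phosphorylation genes rose (adjusted p = 0.00144, and adjusted p = 0.555 with an estimated correlation), 1 of 34 over all genes and 7 adjusted over the list alone. The 1 called over all genes, Ndufv2 (0.28, adjusted p = 0.0497 by limma), lost its call in 21 of 42 alternatives. With the residual axis score as a term it had 0.18 (adjusted p = 0.241). Cytokine and acute phase genes rose (adjusted p = 0.0328, and adjusted p = 0.437 with an estimated correlation), 0 of 25 over all genes and 3 adjusted over the list alone, and Lcn2 had 0.71 ± 0.22 (adjusted p = 0.0802). Lcn2 passed in 5 of 42 alternatives, among them limma within titles O817 to O847 (0.95, adjusted p = 0.00866) and with 3 title runs as the term (0.92, adjusted p = 0.0271). Disease-associated microglia genes rose as a list (adjusted p = 0.00784, and adjusted p = 0.692 with an estimated correlation) with 0 of 30 over all genes and 3 higher and 1 lower adjusted over the list alone, but their direction was down within titles O817 to O847 (adjusted p = 0.0581) and up without the 13 WT CLP libraries (adjusted p = 0.0123). Complement rose at 0.0235, and adjusted p = 0.541 with an estimated correlation, with 0 of 16 over all genes and 1 adjusted over the list alone. Astrocyte genes fell as a list (adjusted p = 0.00396, and adjusted p = 0.327 with an estimated correlation), 1 of 14 over all genes and 3 adjusted over the list alone. Thalamus markers rose at 0.0282 and monoamine neuron markers fell at 0.0257 (adjusted p = 0.541 and adjusted p = 0.456 with an estimated correlation), with 0 members over all genes and 2 and 1 adjusted over the list alone.

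In limma 118 of 18006 genes passed, 70 higher and 48 lower. Without 5xFAD unoperated library 6 limma called 0 genes, with 2169 at an unadjusted p under 0.05, and S100a8 then had a log2 fold change of 1.47 and Sgk1 0.63. Without library 2 or 7 of that group the counts were 77 and 67, and limma voom on all libraries gave 108. Library 2 also ended the calls of Scgb3a1 (0.87), Acer2 (0.49), Cnp (-0.42) and Mlc1 (-0.28), library 7 those of Mag (-0.32) and Mlc1 (-0.32), and library 4 that of Mag (-0.31). With the residual axis score as a term S100a9 (1.25), Scgb3a1 (0.92), Sepp1 (0.38), Cnp (-0.36), Slc6a9 (-0.32), Mlc1 (-0.23) and Mag (-0.22) lost their calls, while S100a8, Sgk1, Acer2 and Gpr17 kept theirs. On that axis 5xFAD unoperated library 6 stood at -2.39 and the others of its group at -0.54 to 1.43. Within titles O817 to O847 (8 against 7) 54 genes passed, 17 of them among the 118, with S100a8 at 1.82 ± 0.26, S100a9 at 1.61 ± 0.20, Scgb3a1 at 1.57 ± 0.13, Sgk1 at 0.93 ± 0.14 and Acer2 at 0.84 ± 0.10, while Cnp (-0.31), Mag (-0.32), Gpr17 (-0.33), Slc6a9 (-0.28) and Sepp1 (0.17) were not called.

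**Figure D4:**
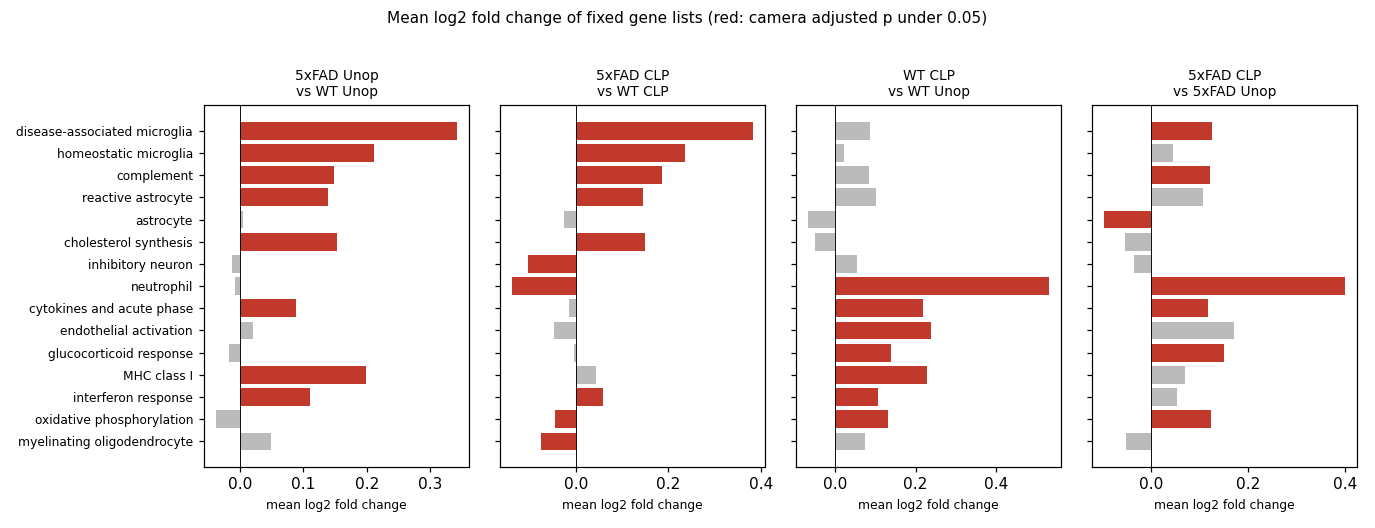
Mean log2 fold change (x axis) of the measured members of 15 gene lists (y axis) in 4 comparisons, red where camera with its preset correlation gave an adjusted p under 0.05 and grey elsewhere. Microglia and cholesterol synthesis lists are red in both genotype comparisons. With an estimated correlation they passed only after CLP, where 21 and 30 libraries were compared instead of 7 and 7. In the fit of all libraries their means were close without and with CLP. They were 0.34 and 0.38 for disease-associated microglia, 0.21 and 0.24 for homeostatic microglia and 0.15 in both for cholesterol synthesis. Within titles O817 to O847, which hold all unoperated libraries, single genes of the first list had smaller genotype values with CLP. Ccl6 had 1.09 without and 0.53 with CLP, Ccl3 0.8 and 0.53, Ctsd 0.56 and 0.26, and Trem2 0.54 and 0.43. No gene passed the test of the difference there. The neutrophil list is red and to the right in both CLP comparisons, with adjusted p = 0.214 in WT and adjusted p = 0.318 in 5xFAD with an estimated correlation.

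The fifth comparison is the one the series title is about, whether amyloid pathology and sepsis act together, tested as the CLP effect in 5xFAD minus the CLP effect in WT. No gene passed the threshold for a difference in response. The smallest adjusted p was 0.963, shared by Pkmyt1 (0.37 ± 0.09), Reps1 (-0.33 ± 0.08), Rrnad1 (-0.35 ± 0.09), Rnaseh2a (0.30 ± 0.08) and Pabpc1l (-0.43 ± 0.12). S100a8, S100a9 and Sgk1, called after CLP in both genotypes, did not pass, and neither did Ccl12 (-0.48 ± 0.16, adjusted p = 0.993) or Nr4a1 (-1.01 ± 0.36, adjusted p = 0.993). Limma gave 0 genes of 18006, with 4.5% of genes at an unadjusted p under 0.05, and limma voom also gave 0. On simulated data the same fit recovered 71% of 1.5-fold and 97.5% of 2-fold differences of this kind. The simulation changed no genes with low means, smoothed the spread of each gene and held no differences between title runs. It therefore does not rule out differences of these sizes in the real data, where Nr4a1 at -1.01 did not pass.

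As lists, 4 groups were lower in the response of 5xFAD than in that of WT, each with 0 members passing over all genes or adjusted over the list alone. MHC class I had a mean difference of -0.16 (adjusted p = 0.00469, and adjusted p = 0.431 with an estimated correlation), and cytokines and acute phase -0.10 (adjusted p = 0.00563, and adjusted p = 0.316 with an estimated correlation). Myelinating oligodendrocyte genes had -0.12 (adjusted p = 0.00159, and adjusted p = 0.316 with an estimated correlation) and immediate early genes -0.19 (adjusted p = 0.00563, and adjusted p = 0.575 with an estimated correlation). Without the 13 WT CLP libraries the adjusted p was 0.0728 for MHC class I and 0.298 for myelinating oligodendrocyte genes, and within titles O817 to O847 it was 0.00196 and 0.0219. The neutrophil list had -0.13 (adjusted p = 0.0736).

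Anesthesia alone was compared with no operation in 5xFAD mice (7 libraries against 7). No gene passed, and the smallest adjusted p was 0.214. Sgk1 had a log2 fold change of 0.58 ± 0.18 (adjusted p = 0.268), the ER chaperone gene Dnajb9 0.41 ± 0.13, Gpr17 -0.38 ± 0.11 and the endothelial lipid transporter gene Mfsd2a -0.45 ± 0.14. For CLP against no operation in 5xFAD, Sgk1 had 0.635, Dnajb9 0.38 and Gpr17 -0.39. Both comparisons use the same 7 unoperated libraries, so alike values are partly built in. Whether sepsis, anesthesia or these unoperated libraries set the changes cannot be told, and they cannot be credited to sepsis alone. The glucocorticoid response list had a mean of 0.13 with anesthesia and 0.15 with CLP, and the neutrophil list 0.14 and 0.40. As lists, oxidative phosphorylation (adjusted p = 5.38e-07, and adjusted p = 0.327 with an estimated correlation) and glucocorticoid response (adjusted p = 0.0262, and adjusted p = 0.585 with an estimated correlation) rose. Mural cell genes (adjusted p = 0.0187, and adjusted p = 0.327 with an estimated correlation) and endothelial genes (adjusted p = 0.02, and adjusted p = 0.541 with an estimated correlation) fell, as did cholesterol synthesis genes (adjusted p = 0.02, and adjusted p = 0.585 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 1 endothelial gene fell and 1 glucocorticoid response gene rose. Limma gave 0 genes with 1849 at an unadjusted p under 0.05, and limma voom gave 0. These groups lie in different title runs, so the comparison rests on the term estimated from the CLP libraries, and without that term 304 genes passed.

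CLP was also set against anesthesia alone in 5xFAD mice (21 against 7). Only 4 of the 21 CLP libraries lie in titles O921 to O940 with the 7 anesthesia libraries. The comparison thus rests on these and on the title series term estimated from the CLP libraries. No gene passed. Lcn2 had a log2 fold change of 0.68 ± 0.25, S100a9 0.93 ± 0.33, the interferon-induced gene Ifitm3 0.50 ± 0.16 and the endothelial gene Pecam1 0.32 ± 0.12. As lists, 13 groups rose and 4 fell, and none held with an estimated correlation. Complement (adjusted p = 7.9e-05, and adjusted p = 0.3 with an estimated correlation), reactive astrocyte (0.000432, and adjusted p = 0.3 with an estimated correlation) and endothelial genes (0.000566, and adjusted p = 0.327 with an estimated correlation) rose with 0 members over all genes or adjusted over the list alone. Neutrophil genes rose (0.000999, and adjusted p = 0.456 with an estimated correlation) with 0 of 12 over all genes and 2 adjusted over the list alone. Oxidative phosphorylation genes fell (0.000377, and adjusted p = 0.509 with an estimated correlation), as did monoamine neuron markers (0.00334, and adjusted p = 0.318 with an estimated correlation), with 0 members either way. Limma gave 0 genes with 600 at an unadjusted p under 0.05 and a smallest adjusted p of 0.644, limma voom gave 0, and without the term for title runs 320 genes passed.

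Sex was compared last. Between the sexes 14 genes passed, 4 higher and 10 lower in males, led by Ddx3y (3.67) and Xist (-4.90). For the genotype effect in females minus that in males limma gave 0 genes, with 1286 at an unadjusted p under 0.05 and a smallest adjusted p of 0.413. For the CLP effect in females minus that in males it gave 0, with 948 and 0.149, and limma voom gave 0 for both.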

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

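Chosen after the result was seen were the tests of library depth and of the residual axis for the 13 libraries, of the count without these, of the residual axis as a term, of the other neutrophil genes and of title runs. The tests of Fgfbp3, of random draws and of the neutrophil mean as a term had their outcomes written down first.

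In groups of 7 libraries, a library was singled out where its gap to the nearest other library took up more of the group's range than Dixon's critical value allows. This was so in 10 of 134 gene and group pairs, and chance gives about 6.7. The ratios were taken on the deposited log2-scale values, while the levels given here are normalized reads. Where all other libraries are at 0 the ratio is 1 whatever the level. In 5xFAD unoperated library 2 Sst was low (580 normalized reads against up to 1060 in the others, ratio 0.57). Gfap was high in 5xFAD unoperated library 6 (1320 against 179 to 411, ratio 0.6). In 5xFAD unoperated libraries 4 and 7, Chil3 stood at 0.995 and Scgb3a1 at 2.09 normalized reads, with all others at 0 (ratio 1 for each). Lcn2 stood at 16.0 in WT unoperated library 1 with all others at 0 (ratio 1). Slc25a22, a mitochondrial carrier, was high in WT unoperated library 4 (159 against 29.5 to 63.1, ratio 0.6), and Ccl6 was high in WT unoperated library 7 (10.8 against 4.79 to 6.73, ratio 0.62). Mmp9 was at 0 in WT unoperated library 5 (1.56 to 4.3 in the others, ratio 0.61). In the anesthesia group Dcn was low in library 1 (82.2 against 139 to 175, ratio 0.68) and Uqcrq was low in library 3 (against 1080 to 1170 in the others, ratio 0.65).

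Wdfy1, Gabra2 and Nnt were lower in the 13 WT CLP libraries titled O795 to O807 (log2 differences of -1.34, -0.95 and -0.54 from the other 17). Library depth is argued against as the whole cause, since its trend in the other 59 libraries, used because the genes were picked for standing apart in the 13, predicts a share of the differences of at most 0.0603 (upper 95% limit), and so is the residual axis, with at most 0.0736. A strain variant may account for it, since stocks of C57BL/6 are known to differ at Nnt and Gabra2 and in the copy number of Ide and its neighbour Fgfbp3. Ide was higher by 0.41 (permutation p = 3e-05, two-sided) and Fgfbp3 by 0.16 (permutation p = 0.037), but the ranges of both genes overlapped with those of other libraries, so this evidence is weak. The rise of Ide was known before the test of Fgfbp3 was written down, so only Fgfbp3 was a test set in advance. The labels give no substrain, a difference in how these 13 libraries were made stays open, and beside the strain variant no biological explanation was tested.

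CLP called 1555 genes in WT and 118 in 5xFAD, while the test of the difference called 0, and without the 13 libraries the count in WT was 140, so they may carry most of the excess. The number of WT CLP libraries cannot be told apart from this, although the bound written down first was met: 20 random draws that left out 13 of the 21 WT CLP libraries of the first title series gave a median of 720.5 genes, more than 1.5 times 140. That bound left out the spread of single draws, 69 to 1794 with 1 at or below 140, and was set aside after the draws were seen. Whether RNA quality or handling also contributes stays open, since neither was measured. With the residual axis score as a term 17 genes passed in WT and 13 in 5xFAD. That score also carries differences between the groups, so the term can take out an effect of CLP itself and the drop shows no cause. That axis was taken from the same data and could hold biology too, so a lasting difference between the genotypes in their response to sepsis stays open.

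S100a8, S100a9, Selp, Cp, which encodes the copper transport protein ceruloplasmin, and Sgk1 were higher after CLP in WT. The call of Cp (0.41 ± 0.11) ended without WT unoperated library 2 (0.39) or 5 (0.36), and those of Selp, Cp (0.41) and Sgk1 (0.47) ended with the residual axis score as a term. A difference between the 3 title runs is argued against as the whole cause, since 5 of the 5 genes passed within titles O817 to O847. The genes were picked from a fit that held these same libraries, so this is no independent check. Sizes also differed by run: Cp had 0.70 ± 0.09 there. Selp averaged 7.5 ± 5.6 normalized reads in the WT CLP libraries of titles O817 to O847, above its mean over all WT CLP libraries. S100a8, S100a9 and Sgk1 stayed close to their values over all libraries. Inside that run the unoperated libraries hold titles O824 to O837, with CLP libraries only before and after them. Handling in blocks of titles within the run therefore stays open. Neutrophil RNA may account for S100a8 and S100a9 in WT, since 7 of the other 10 neutrophil genes also passed. In 5xFAD, where S100a8 (1.33) and S100a9 (1.21) rose too, they were the only neutrophil list genes that passed. This account thus rests on WT alone. For Selp, Cp and Sgk1 it cannot be told apart from a change in brain cells, because with the neutrophil mean as a term the log2 fold change of Cp went to 0.19 ± 0.12, a ratio of 1.56 to its SE, while Sgk1 had 0.47 ± 0.14 (adjusted p = 0.0312) and Selp a ratio of 2.65 (adjusted p = 0.101).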

How the results depend on the processing

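Chosen after seeing the data were the fits without the 13 WT CLP libraries, within titles O817 to O847, with 3 title runs, with the cerebellum or residual axis score, with changed or left-out libraries of doubtful sex, and voom. Except for fits with fewer libraries, where the smaller number is built in, the cause of each change was not tested. For named genes the alternatives chosen beforehand gave 4858 values on the same side of the threshold, 368 that lost their call, 14 that gained one and 14 that moved, and the added ones 1081, 279, 10 and 6, with 3 reversed: Wdfy1 in WT after CLP had 0.084 without the 13 libraries, 0.117 within titles O817 to O847 and 0.113 there without 5xFAD unoperated library 2. For 5xFAD against WT without operation (4 genes), only the compared groups gave 1 gene and males 1, both Thy1. For 5xFAD against WT after CLP (167), title series 2 gave 1 (Thy1), females 27, males 35, the fit without the 13 libraries 42 (35 shared), titles O817 to O847 2, and these without library 2 4. For CLP in WT (1555), no title series term gave 287 (286 shared), females 0 in limma (2419 at an unadjusted p under 0.05; voom gave 1795 on all libraries), males 10, sample weights 2499, without the 13 libraries 140 (120 shared), titles O817 to O847 64, these without library 2 133, 3 title runs 292 and the residual axis 17 (16 shared). Leaving out a single library gave 679 (WT unoperated 3) to 1882 (WT unoperated 1). For CLP in 5xFAD (118), no title series term gave 15, series 1 alone 189, females 0 in limma (1930 unadjusted; voom gave 108 on all libraries), the higher-mean genes 205, without the 13 libraries 72, titles O817 to O847 54 (17 shared), these without library 2 63, 3 title runs 78, the cerebellum score 69 and the residual axis 13. Leaving out a single library gave 0 (5xFAD unoperated 6; 2169 unadjusted) to 163 (5xFAD unoperated 3). The difference between the genotypes in the CLP effect (0) had 1 gene in females, Pcdha5. Anesthesia against no operation (0) had 304 without the title series term, 1 in males (Il20ra), 1 with quantile normalization (Tubb2a) and 2 with 3 title runs (Scgb3a1 and Alas2), and CLP against anesthesia (0) had 320 without that term. The sex differences had 0 to 1 gene: Mea1 for genotype without 5xFAD unoperated library 3, and the predicted gene 9430041J12Rik for CLP without WT or 5xFAD unoperated library 3. These genes fall outside the rule and were named after their values were seen. Of 266 list tests camera called 66, with an estimated correlation 5 and fry 11. Title series 2 has no unoperated libraries, so comparisons with them could not be fitted there, and anesthesia against no operation could not be fitted with only its groups and that term. At this depth a gene at 0 reads in a library could have up to 3.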

Other observations

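The comparison of both genotypes within titles O817 to O847, the overlap of their CLP genes and the correlations with Thy1 were tests chosen after the results were seen, and the genes in these paragraphs were named after their values were seen.

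Within titles O817 to O847, the only run that holds both genotypes with and without CLP, Lrg1, Scgb3a1, Vwf, Cebpd and Ly6a rose after CLP in both genotypes. Lrg1, an acute phase glycoprotein also made by endothelium, rose from 8.47 ± 3.83 to 58.7 ± 25.1 normalized reads in WT (SD, n = 7 and 8; log2 fold change 1.31 ± 0.19 by limma, adjusted p = 0.00028) and from 10.5 ± 10.3 to 60.3 ± 27.1 in 5xFAD (1.31 ± 0.19, adjusted p = 0.000269). In the fit of all libraries the call of Lrg1 in WT (0.75 ± 0.23) ended without WT unoperated library 2, 3, 4 or 5 (0.67, 0.78, 0.71 and 0.75). Scgb3a1 rose from 0.541 ± 0.808 to 20.7 ± 11.4 in WT and from 0.299 ± 0.79 to 29.5 ± 13.3 in 5xFAD. Vwf, the von Willebrand factor of endothelium and platelets, rose from 11.7 ± 4.0 to 29.6 ± 9.02 and from 12.8 ± 4.86 to 34.2 ± 16.2. Cebpd, a transcription factor of the acute phase response, rose from 22.8 ± 9.61 to 60.0 ± 18.1 and from 26.1 ± 10.9 to 57.7 ± 11.8, and the endothelial gene Ly6a from 157 ± 24.8 to 291 ± 63.9 and from 146 ± 39.2 to 265 ± 51.9. In the limma fit of all libraries the call of Ly6a in WT (0.48, adjusted p = 0.0459) ended in 14 of 42 alternatives. Among these were the fits without WT unoperated library 2, 3, 4, 5, 6 or 7.

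In this run 20 genes were called higher after CLP in both genotypes, of 50 in WT and 41 in 5xFAD, where independent calls would share 0.114. Of 14 and 13 called lower 2 were shared, Qdpr and Smim13, where 0.0101 would be. The genotypes share no library here, but both fits draw on the same variance estimate and the same run of titles. In both, the unoperated libraries lie within titles O824 to O837 with no CLP library among them, so an effect of handling by title could be shared. The test of the difference called 0 genes in limma within these titles and in voom over all libraries, where limma had 4.5% of genes at an unadjusted p under 0.05.

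Cerebellar transcripts differed between the title series, as in the medians of Car8, a Purkinje cell gene (45.5 normalized reads in the first series and 390 in the second), and Cbln1 (71.6 and 342). Single libraries overlapped, with Car8 up to 185 in the first series and down to 35.7 in the second.

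Among the 35 5xFAD libraries Cst7 rose with Thy1 (Pearson r = 0.68, permutation p = 2e-05, adjusted p = 2e-05 over 3 relations; Spearman rho = 0.75, p = 1e-05, the smallest these permutations can give). Without the 2 libraries farthest from the median of Thy1 r was 0.73, in females 0.64 and in males 0.71. Within title series 1 r was 0.67 (p = 3e-04), and in series 2 r was 0.74 (p = 0.013) while rho was 0.49 (p = 0.13). Gfap (r = 0.86, adjusted p = 1.5e-05; rho = 0.79) and the mean of the disease-associated microglia list (r = 0.75, adjusted p = 1.5e-05; rho = 0.76) rose with Thy1 as well, each r at a permutation p of 1e-05. In series 2 the list had r = 0.77 (p = 0.019), 0.42 without the 2 farthest libraries, and rho = 0.28 (p = 0.4). In the 37 WT libraries r was -0.19 for the list (p = 0.26) and 0.55 for Gfap (p = 0.00032). With each title run and group centred on its own mean, r for Gfap was 0.33 in WT (p = 0.076) and 0.91 in 5xFAD (p = 1e-04, the smallest these permutations can give). Whether transgene dose sets the microglial response stays open, since r = 0.68 is the relation to be explained and no separate test was run. Dissection, age or amyloid load were not tested.

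Other splits of the same samples, 100 for each comparison with the real one included, were fitted in the same way. A random split is argued against as the source of the counts for CLP in WT (1555 genes, as many in 1 of 100, highest other 3), 5xFAD against WT after CLP (167, 1 of 100, highest other 17) and CLP in 5xFAD (118, 1 of 100, highest other 21). These splits ignored the title runs, while all unoperated libraries lie in a single run. Differences between runs, blocks of titles or single libraries could therefore still give such counts. For 5xFAD against WT without operation (4, 3 of 100) the bound set beforehand was met, but chance is not excluded as the source of the count. This share is among several that were not corrected for their number, and another split gave 368, which points to a structure of the samples. The counts of 0 were matched by 100 of 100 splits. There the highest other was 185 for the difference in the CLP effect, which also points to a structure of the samples, 4 for anesthesia against no operation, 18 for CLP against anesthesia, and 3 and 15 for the sex differences in the effects of genotype and of CLP. What sets the splits with 368 and 185 genes apart was not tested.

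The 5xFAD CLP libraries 7 and 8 carried the sex-linked transcripts of the opposite sex to their labels. Library 7, labelled male, had 960 normalized reads of Xist and 1.74 of Y-linked genes, and library 8, labelled female, had 2.51 and 380. Other females had up to 1330 of Xist and other males 0.83 to 24.3.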
